A study of Homo sapiens with 19 samples.

How the data were processed

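Messenger RNA was profiled in 19 samples, 1 array for each of 19 cell lines, all derived from MDA-MB-231, a human breast cancer line. The labels placed 1 array in the parental group, 2 in the modal-ploid and 2 in the hyper-ploid sublines, 3 in the weakly and 4 in the strongly bone-metastatic lines, and 3 in the weakly and 4 in the strongly lung-metastatic lines. A modal-ploid and a hyper-ploid subline came from each of the lines 1833 and 4175, per the labels. The weakly bone-metastatic line titled 2296 was called 2297 in its cell line label and in the series' design text. It is written here as 2296, and its group was the same under either name. Per the labels' protocols, cells were harvested before confluence, total RNA was taken with a column kit, and biotin-labelled cRNA was prepared by the standard Affymetrix procedure. The platform had 22283 probe sets, each a group of short probes. The image analysis, the array normalisation and the software the authors used are not given in the sources used here.

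The deposited values were linear ratios between 0.00115 and 361, and each array's median ratio lay between 0.925 and 1.03. How the authors made these ratios was read from the values alone. In the 10 arrays of the parental line, the 1833 ploidy pair and the 7 bone lines, the median over arrays was 1 for 91.6% of probe sets (tolerance 1e-06). In the other 9 arrays, the 4175 ploidy pair and the 7 lung lines, that share was 0.0224%. The authors' ratios were therefore treated as 2 separately divided sets, within each of which every probe set had 1 divisor. A ratio can be compared within a set only. The second set's divisor may rest on arrays not used here.

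Within an array the deposited ratios were whole multiples of a step once each probe set's divisor and each array's factor were taken out. With steps of 0.1 signal units and a tolerance of 0.01 steps at low values, signals were recovered for 22187 of 22283 probe sets (99.6%). The largest distance from a whole step was 0.0443. Shuffling the probe sets within each array left 0.651% of the first set and 1.55% of the second set recovered. The log2 divisors of the 2 sets, solved separately, correlated with r = 0.972 across probe sets. A fixed divisor of 10 was found for 1472 probe sets. The 96 probe sets not recovered were left out. The design fixed beforehand had assumed log or linear expression values, so the recovered signals, and not the ratios, were analysed as linear values, and the deposited ratios on a log2 scale served as an alternative chosen after seeing the data.

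The recovered signals had a mean, after removing 2% of probe sets at each end, of 473 to 477 on 15 arrays and of 308 to 344 on the 4 ploidy arrays. Median signals were 121.8 to 161.6 on those 15 arrays and 88.1 to 96.5 on the 4 ploidy arrays. The biotin-labelled spike-in controls were averaged on the log2 scale before any scaling between arrays. Means were 10.5 to 10.9 for parental and bone lines, 9.38 to 10.1 for lung lines and 8.71 to 8.93 for ploidy sublines. Part of the low level of the ploidy sublines goes with their lower overall signal, which the later scaling removes. These spike-in levels moved with the groups, so an effect of array handling cannot be told apart from target organ or from ploidy subline against line of origin. The difference of the strong-against-weak differences between bone and lung lines cancels an effect shared by all bone lines or all lung lines.

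Signals were scaled to a common array median and expressed as log2(signal + 16), so that a difference understates the change of a dim gene. A probe set was kept if it lay above its own array's 40th percentile on at least 2 of the 19 arrays, which 16277 did. In the platform annotation 19071 probe sets had 1 gene symbol, 1043 had several and 2169 had none, and only those with 1 were named. Of the former, 19059 had a gene identifier in the RefSeq table for GRCh38.p14, and 0 symbols needed updating. For each of 11963 named genes the kept probe set with the highest mean over the 19 arrays stood for the gene, which left 9544 genes to test. Where a gene's arrays in the dimmer group all lay at or below the 40th percentile, the fold is given as at least the brighter group's mean over that percentile level.

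Group differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over the 9544 genes of a comparison, with a threshold of 0.05. The ploidy comparison used the 4 ploidy arrays with the line of origin as a block, which left 1 residual degree of freedom before moderation and a prior of 10.0 degrees. The block pairs sublines of the same cell line, as the labels give it. The other comparisons used the 14 lines of the 4 strong and weak groups with 1 mean per group, 10 residual degrees and a prior of 3.86. These were strong against weak bone lines, strong against weak lung lines, strong bone against strong lung lines, and the difference between the first pair of differences. The p-values measure the spread between lines with 1 array each, which holds technical spread too. They treat the lines as independent, though all derive from MDA-MB-231. Descent shared within a group was not taken into account, and would make the p-values too small.

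Gene lists written before the data were examined, 20 in all with 518 genes of which 418 were tested, were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 20 lists. Each was also run with an estimated correlation. The lists were bone metastasis genes, lung metastasis genes, mitosis, DNA replication, p53 targets, YAP targets, TGF-beta response, interferon-stimulated genes, NF-kB and inflammatory cytokines, collagens and matrix, matrix proteases and inhibitors, epithelial markers, mesenchymal markers, hypoxia and glycolysis, ribosome biogenesis and MYC targets, cholesterol synthesis, actin cytoskeleton, immediate early and stress genes, and markers of leukocytes and of endothelial and stromal cells. The bone and lung metastasis lists came from earlier work on sublines of the same cell line and are not independent evidence here. Some genes, such as MMP1, SPARC and TNC, are shared between lists, so the list results are not independent of each other.

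Named genes followed a rule fixed beforehand. It took the 8 largest and 8 smallest log2 differences among genes past the threshold whose groups did not overlap (for ploidy, with the same sign in both lines of origin). Where fewer than 8 passed in a direction, the largest others filled up to 5, as values only. Up to 3 members of each list with the smallest p were added, and all members of both metastasis lists could be named. Some genes under this rule are not reported here, which leaves 1 place open on the higher side for ploidy and 1 on the lower side for strong bone against strong lung lines, and some places among list members.

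The fits were tested on simulated data for 9544 genes, 100 of them changed by 1 and 100 by 2 on the log2 scale. Gene means were the real ones, and the noise of each gene was drawn independently with its moderated spread from limma. Moderated spreads vary less between genes than unmoderated ones, most of all with 1 residual degree of freedom. The numbers recovered for the ploidy design may therefore be too high. The recovered numbers were 59 and 100 for the ploidy design with 14 false calls, 43 and 94 for bone with 2 false calls, 47 and 97 for lung with 12, 49 and 95 for strong bone against strong lung with 4, and 8 and 76 for the difference of differences with 3. A simulated list moved by 0.5 was called, and it was the 1 list called of 20. Simulated genes were drawn independently, so this cannot show how often a list of correlated genes is called wrongly with the preset correlation. In the strong and weak lines the estimated correlation within lists ran from 0.034 (endothelial and stromal markers) to 0.59 (DNA replication). The neighbour correlation described among the further observations was -0.0222 in simulated data with no moved block, 0.0342 with 1 block of 200 genes moved by 0.5 and 0.222 with 9 such blocks, the last added after the single block had been found hard to see.

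Alternatives written before the data were examined were quantile normalisation, centring on the array median, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, all probe sets, a trend with a robust prior, an adjusted p threshold of 0.1, other arrays in the fit, no block, and leaving out each line in turn. Scaling to a common trimmed mean and log2 of the deposited ratios were chosen after seeing the data. Signal recovery and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.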

Results

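Gene expression was measured on oligonucleotide arrays in 19 lines of one ancestry, the MDA-MB-231 breast cancer line and sublines taken from it. Strongly and weakly metastatic lines had been grouped by the organ they colonise. There were 4 strong and 3 weak lines for bone and 4 strong and 3 weak lines for lung. The lines 1833 (bone) and 4175 (lung) had each also given 1 subline of modal and 1 of raised DNA content. The title and design of the series ask how a doubling of ploidy relates to metastasis. The comparisons are hyper-ploid against modal-ploid, strong against weak for each organ, and the relation between these. Each line had 1 array. Levels are given as log2(signal + 16) and differences on that scale, and adjusted p-values come from limma over 9544 genes.

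**Figure D1:**
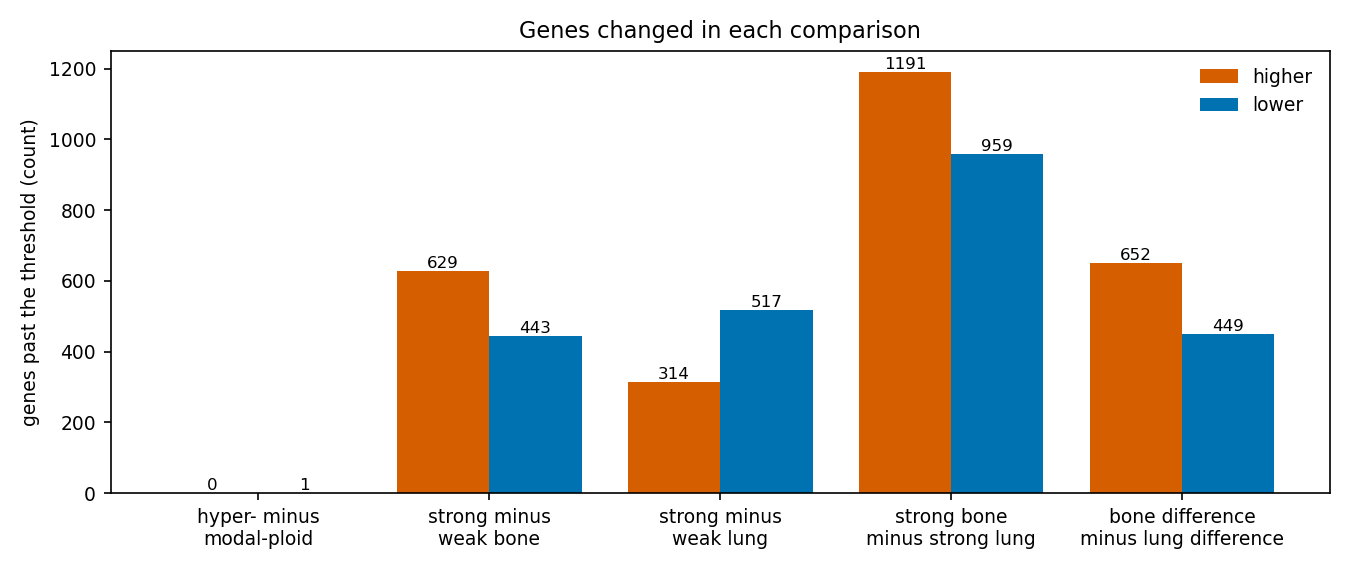
Bars give the number of genes past an adjusted p threshold of 0.05 (limma, 9544 genes tested) in each comparison, split into higher and lower. The ploidy comparison has 1 gene, and strong bone against strong lung lines, 4 of each, has 1191 higher and 959 lower.

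PRKCZ, which encodes the atypical protein kinase C zeta involved in cell polarity, was lower in hyper-ploid than in modal-ploid sublines, with a log2 difference of -2.66 (SE 0.30, adjusted p = 0.0224, n = 2 against 2). Its mean signal was 34.7 in the hyper-ploid and 304 in the modal-ploid sublines, at least 3.32-fold lower, and its log2 difference was -3.13 in the 1833 pair and -2.19 in the 4175 pair. It was the 1 gene that passed the threshold, and 506 genes had an unadjusted p under 0.05 where 477 would by chance. Arrays were scaled to a common median, so a change shared by most genes would not be seen here. The other genes named by the size of their mean difference, with the same sign in both lines, did not pass. On the lower side these were ALDH3A1, an aldehyde dehydrogenase (-2.35, SE 0.63, adjusted p = 0.366, with -0.47 in 1833 and -4.24 in 4175), and the collagenase MMP1 (-2.10, SE 0.42, adjusted p = 0.253). They also were POGZ, a zinc finger protein of chromatin (-1.85, SE 0.35, adjusted p = 0.253), and the elastic fibre protein FBLN5 (-1.75, SE 0.28, adjusted p = 0.253). On the higher side they were the matricellular SPARCL1 (1.72, SE 0.30, adjusted p = 0.253) and the kinase TAOK1 (1.45, SE 0.33, adjusted p = 0.333). There were also the glypican GPC4 (1.44, SE 0.30, adjusted p = 0.255) and the Src family kinase FGR (1.44, SE 0.27, adjusted p = 0.253). SPARCL1 and GPC4 lay at or below the 40th percentile of signal on all 4 arrays. The dimmer arrays of ALDH3A1, FBLN5 and TAOK1 did too, which bounds their folds at no less than 1.81, 1.11 and 1.27, and for FGR no bound above 1 could be given. The PRKCZ call held in 4 of 11 alternative settings, with adjusted p from 6.55e-10 with a stricter filter to 1.0 with no block. It was lost in either pair alone with the spread pooled over the 19 arrays (adjusted p = 0.491 in 1833 and 1.0 in 4175).

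**Figure D2:**
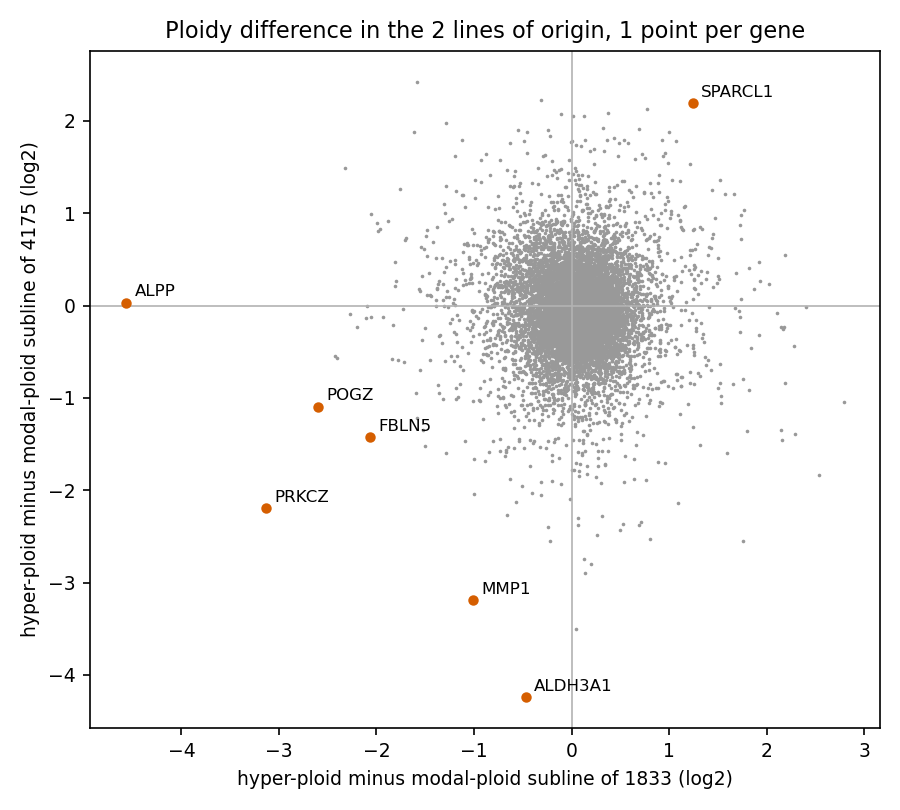
Each point is 1 of 9544 genes, with the log2 difference between the hyper-ploid and modal-ploid sublines of 1833 on the horizontal axis and that of 4175 on the vertical axis. PRKCZ lies low in both pairs (-3.13 and -2.19), while ALPP is low in the 1833 pair alone (-4.56 and 0.03).

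The epithelial markers were shifted lower in the hyper-ploid sublines as a list (mean log2 difference -0.38 over 18 genes, adjusted p = 0.000161), with the keratins KRT19 at -1.10 (SE 0.30) and KRT7 at -0.67 (SE 0.27). So were the interferon-stimulated genes (mean -0.28 over 28 genes, adjusted p = 0.00108), with the transcription factor IRF7 at -0.66 and the antiviral TRIM22 at -0.82. The lung metastasis genes (mean -0.38 over 15, adjusted p = 0.00263) held MMP1 at -2.10, the interleukin 13 receptor IL13RA2 at -1.02 and the latent TGF-beta binding protein LTBP1 at -0.70. The YAP targets (mean -0.24 over 20, adjusted p = 0.00537) held the forkhead factor FOXF2 at -0.62 and the growth factor carrier IGFBP3 at -0.63. The mitosis genes (mean -0.15 over 32, adjusted p = 0.032) held the kinesin CENPE at -0.68. No member of these 5 lists passed over all genes, and adjusted over the list alone 2 of the lung metastasis genes and 0 of the others passed. The 5 list calls were lost with an estimated correlation, each with adjusted p = 0.973. With 1 residual degree of freedom that variant could hardly call any list, so it cannot decide about these calls. Without the 4175 pair, and with the spread pooled over 19 arrays, the epithelial list kept its call, which was lost with no filter (adjusted p = 0.0598). The other 4 lost theirs, with adjusted p = 0.554 for interferon-stimulated genes, 0.423 for lung metastasis genes and YAP targets and 0.458 for mitosis. In the 1833 pair the medians were still -0.28 for the lung metastasis genes (11 of 15 lower) and -0.11 for YAP targets. The bone metastasis genes were not called (mean -0.35 over 8, adjusted p = 0.159), nor were the markers of leukocytes (adjusted p = 0.767) or of endothelial and stromal cells (adjusted p = 0.9).

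Across single genes, the ploidy differences of the lines of origin were largely unrelated. The SD of the log2 differences over genes was 0.42 in the 1833 pair and 0.50 in the 4175 pair. In the 1833 pair 317 genes differed by over 2-fold (162 higher and 155 lower in the hyper-ploid subline) and in the 4175 pair 497 did (212 higher and 285 lower), with no replicate check. Over 2-fold in the same direction in both were 28 genes, against 8.23 if the pairs were independent. The latter number takes every gene as equally likely to differ, and is too low if some genes vary more in both pairs. An excess over it is therefore not established. Across all genes, which are not independent replicates, the differences of the pairs correlated with Spearman's correlation -0.0349 and Pearson's r = -0.0245. The NF-kB and inflammatory cytokines had a median difference of 0.56 in the 1833 pair, above all 10000 random lists matched on expression, and of -0.59 in the 4175 pair, below all 10000. The hypoxia and glycolysis genes also stood at opposite ends, with 0.26 in 1833 (percentile 99.6) and -0.37 in 4175 (percentile 0.36). Other lists stood low in both pairs, with percentiles in 1833 and 4175 of 0.22 and 0 for epithelial markers, 0.21 and 0.4 for lung metastasis genes and 0.52 and 0.39 for YAP targets. These percentiles describe single arrays.

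In the strongly bone-metastatic lines the genes with the largest rises were ADAMTS1, a secreted metalloprotease (log2 difference 4.68, SE 0.40, adjusted p = 2.13e-05, at least 12.8-fold), and NAP1L3 of the nucleosome assembly family (4.09, SE 0.60, adjusted p = 0.000905, at least 5.0-fold), with n = 4 against 3 lines. Next came the activin antagonist FST (3.78, SE 0.33, adjusted p = 2.22e-05) and the cytokine IL11 (3.52, SE 0.62, adjusted p = 0.0032). The stress-induced cytokine GDF15 (3.20), the proteoglycan SRGN (3.01), PLAC8 (2.92) and C4BPB, a chain of the complement C4b-binding protein (2.91), followed. The largest falls were in SERPINA1, which encodes the antiprotease alpha-1-antitrypsin (-5.83, SE 0.66, adjusted p = 0.000137), and the iron-siderophore carrier LCN2 (-5.15, SE 0.31, adjusted p = 7.57e-07). Also lower were complement C3 (-4.57, SE 0.64, adjusted p = 0.000673, at least 11.2-fold lower), the chemokine CCL20 (-4.18, at least 5.88-fold lower) and the acute phase antiprotease SERPINA3 (-4.13). PTPRN2, a protein of secretory granules (-3.84, SE 1.11, adjusted p = 0.0404), the cell junction protein PPL (-3.83, at least 4.09-fold lower) and the matrix protein TGFBI (-3.82) also fell. In all, 1072 genes passed, 629 higher and 443 lower (58.7% higher). With arrays scaled to a common trimmed mean, a choice made after seeing the data, 1509 passed, 707 higher and 802 lower (46.9% higher).

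The bone metastasis genes rose as a list, with 7 of 8 measured members higher, 0 lower and a mean log2 difference of 2.82 (adjusted p = 9.15e-11). Adjusted over the list alone all 8 passed, and with an estimated correlation the list's adjusted p was 0.018. The list came from earlier work on sublines of the same line and is not independent evidence. Besides ADAMTS1, FST, IL11 and SRGN its members CCN2, a matricellular protein (2.44, SE 0.24), the chemokine receptor CXCR4 (2.36, SE 0.33) and the growth factor FGF5 (0.95, SE 0.28, adjusted p = 0.0432) rose, and MMP1 stood at 1.80 (SE 0.55, adjusted p = 0.0514).

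The NF-kB and inflammatory cytokines fell, with 8 of 21 members lower and 0 higher (mean -1.33, adjusted p = 4.1e-07, 11 adjusted over the list alone). Among them were the chemokine CXCL1 (-3.49, SE 0.60) and the granulocyte growth factor CSF3 (-3.37, SE 0.56). With an estimated correlation the adjusted p was 0.306. The YAP targets rose (7 of 20 higher and 1 lower, 12 adjusted over the list alone, mean 0.64, adjusted p = 8.08e-05). It had CCN2 and the transmembrane protein CRIM1 (1.80, SE 0.17) higher. Its adjusted p was 0.567 with an estimated correlation. The immediate early and stress genes rose (5 of 26 higher and 0 lower, 9 adjusted over the list alone, mean 0.46, adjusted p = 0.00257, and adjusted p = 0.6 with an estimated correlation). The phosphatase DUSP1 stood at 2.30 (SE 0.27) and IER2 at 0.93 (SE 0.18). The ribosome biogenesis and MYC targets had a higher mean (0.39 over 20, adjusted p = 0.00729, and adjusted p = 0.652 with an estimated correlation). WDR43, a ribosome assembly factor (0.91, SE 0.25), and MYC itself (0.66, SE 0.20) were the 2 members that passed, 1 adjusted over the list alone. The cholesterol synthesis genes likewise (mean 0.48 over 20, adjusted p = 0.00658, and adjusted p = 0.652 with an estimated correlation) had 1 member past the threshold, FDPS (0.81, SE 0.25), and 0 adjusted over the list alone. The desaturase SCD stood at 1.77 (adjusted p = 0.0671) and the isomerase IDI1 at 1.04 (adjusted p = 0.0725). The hypoxia and glycolysis genes were shifted lower (2 of 25 higher and 4 lower, 13 adjusted over the list alone, mean -0.26, adjusted p = 0.0432, and adjusted p = 0.759 with an estimated correlation). ALDOC (-1.58, SE 0.19) and TPI1 (-0.99, SE 0.20), glycolytic enzymes, and the oxygen-sensing hydroxylase EGLN3 (-1.40, SE 0.22) fell. Rises and falls here are strong against weak lines, and do not tell which group departed from the parental line. Relative to the weak bone lines, the parental array stood at -0.93 for the NF-kB list, 0.63 for YAP targets and 0.84 for cholesterol synthesis. It stood at 0.23 for the ribosome list and -0.19 for the hypoxia list. For these lists it lay nearer to the strong than to the weak lines. For the immediate early genes, at -0.17, it lay nearer to the weak lines.

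Of the lists not called between strong and weak bone lines, the lung metastasis genes had 4 of 15 lower and 0 higher (5 adjusted over the list alone, adjusted p = 0.283). The lower ones included the transcriptional regulator ID1 (-1.80, SE 0.30) and the matrix protein TNC (-1.93, SE 0.39). Their mean of -0.35 and median of 0.11 differed in sign. The epithelial markers (1 higher and 4 lower of 18, adjusted p = 0.217) moved both ways, with the junction protein JUP (-2.93) and KRT7 (-1.77) lower and the sorting adaptor AP1M2 (2.04) higher. Among the mesenchymal markers (2 higher and 2 lower of 17, adjusted p = 0.428) fibronectin FN1 fell (-1.74) and fibrillin FBN1 rose (0.91). In the collagens and matrix list, 4 were higher and 4 lower of 30 (adjusted p = 0.646). The actin cytoskeleton genes (3 higher and 2 lower of 25, adjusted p = 0.428) included the non-muscle myosin MYH10 (2.70) and the calponin CNN3 (1.39) among those that rose and the actin-binding CALD1 (-1.26) among those that fell. The p53 targets had 3 higher and 1 lower of 16 (adjusted p = 0.646), with GDF15 and the damage-inducible GADD45A (1.91) among the higher. The mitosis genes had adjusted p = 0.646, the DNA replication genes 0.567, the interferon-stimulated genes 0.567, the TGF-beta response 0.646 (mean -0.05, median 0.01) and the matrix proteases 0.695 (mean 0.25, median -0.08). Markers of other cell types were not called. The leukocyte list had 0 higher and 2 lower of 15 (adjusted p = 0.117), LAPTM5 at -1.55 and HCLS1 at -1.38, and the endothelial and stromal list 0 higher and 2 lower of 11 (adjusted p = 0.283), with the adhesion molecule PECAM1 at -1.60.

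The count of genes past the threshold between strong and weak bone lines depended on single lines. It was 545 without 2293, 532 without 2295 and 605 without 2296, each a weak line, and 705 without the strong line 2274. Of the named genes, FDPS, FGF5, MYC, PTPRN2, WDR43, FBN1, FN1 and HCLS1 lost their calls without at least 1 line, with the highest adjusted p 0.179, 0.193, 0.147, 0.111, 0.0911, 0.0940, 0.0786 and 0.0540, and the hypoxia list reached adjusted p = 0.166 without 2296. Under the other settings FGF5, FBN1, FDPS, MYC and PTPRN2 also lost theirs in at least 1, at most at 0.0936, 0.0556, 0.0650, 0.0639 and 0.0530.

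In the strongly lung-metastatic lines MMP1, a collagenase (log2 difference 6.82, SE 0.55, adjusted p = 1.75e-05, at least 32.3-fold), and the matricellular protein SPARC (6.72, SE 0.42, adjusted p = 2.77e-06, at least 32.2-fold) rose most. They went from at or below the 40th percentile in all 3 weak lines to mean signals of 3236 and 3222 in the 4 strong lines. IL13RA2 (4.97, SE 0.73, adjusted p = 0.000938, at least 14.8-fold) and the transcription factor SOX4 (4.35, SE 0.41, adjusted p = 5.19e-05, at least 5.96-fold) followed. PTPRN2 (4.34, SE 1.11, adjusted p = 0.0266, at least 4.88-fold), SPANXB1 of a testis-expressed family (3.84, SE 0.91), CSF3 (3.33, SE 0.56, at least 3.93-fold) and the guidance receptor ROBO1 (3.31, SE 0.45, at least 1.87-fold) also rose. The cytokine IL32 (-4.31, SE 0.47, adjusted p = 0.00013, at least 5.0-fold lower), LCN2 (-3.94, SE 0.31, adjusted p = 1.64e-05), the hyaluronan-degrading protein CEMIP (-3.54) and PDZK1IP1 (-3.50) fell most. These were followed by C3 (-3.21, SE 0.64), the transporter ABCC3 (-3.17, at least 3.78-fold lower), the chemoattractant RARRES2 (-3.17, at least 3.13-fold lower) and the matrix protein MATN2 (-3.04, at least 5.99-fold lower). In all, 831 genes passed, 314 higher and 517 lower (37.8% higher). Quantile normalisation gave 562 higher and 593 lower (48.7% higher).

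The lung metastasis genes rose as a list (12 of 15 higher, 0 lower, 13 adjusted over the list alone, mean 2.67, adjusted p = 5.85e-17), and kept the call with an estimated correlation (adjusted p = 0.00161). This list too came from sublines of the same line and is not independent evidence. Besides MMP1, SPARC and IL13RA2 it held the growth factor EREG (2.70, SE 0.23), the actin-bundling FSCN1 (2.53, SE 0.29), and TNC (2.41, SE 0.39). Others of the 12 were the cyclooxygenase PTGS2 (2.37, SE 0.33, at least 1.74-fold), the mannosidase MAN1A1 (2.29, SE 0.31, at least 1.91-fold), ID1 (1.96, SE 0.30), ANGPTL4 (1.91, SE 0.44, at least 2.27-fold), the adhesion molecule VCAM1 (1.90, SE 0.46, at least 3.23-fold) and LTBP1 (1.71, SE 0.31). The gelatinase MMP2 stood at 1.85 (SE 0.67, adjusted p = 0.11). The bone metastasis genes rose as well (3 of 8 higher, 0 lower, 4 adjusted over the list alone, mean 1.71, adjusted p = 5.91e-05). The 3 were MMP1, ADAMTS1 (1.56, SE 0.40, at least 1.04-fold) and CCN2 (1.44, SE 0.24), with IL11 at 1.97 (adjusted p = 0.0677). The list's median was 1.15, and its adjusted p was 0.0821 with an estimated correlation. MMP1, the largest rise, belongs to both metastasis lists.

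The collagens and matrix list rose (10 of 30 higher and 2 lower, 15 adjusted over the list alone, mean 0.76, adjusted p = 8.95e-05, and adjusted p = 0.0821 with an estimated correlation). SPARC, the laminin LAMA4 (2.59, SE 0.27, at least 2.79-fold) and the collagen COL6A3 (1.67, SE 0.23) were higher. SPARC and TNC are shared with the lung metastasis list, and the median of the collagens list was 0.46. The matrix proteases and inhibitors rose (4 of 23 higher and 1 lower, 12 adjusted over the list alone, mean 0.65, adjusted p = 0.0113, and adjusted p = 0.230 with an estimated correlation). The serpin SERPINE2 was higher (2.63, SE 0.23) and the cathepsin CTSS lower (-2.37, SE 0.35). The protease list also held MMP1, a member of both metastasis lists and the largest rise named above, and its median was 0.36. The TGF-beta response rose (6 of 21 higher and 1 lower, 11 adjusted over the list alone, mean 0.69, adjusted p = 0.00887, and adjusted p = 0.285 with an estimated correlation). The Notch ligand JAG1 (2.41, SE 0.26) was among the 6. The mitosis genes had a higher mean (0.29 over 32, adjusted p = 0.000324, and adjusted p = 0.607 with an estimated correlation). RACGAP1, a cytokinesis regulator (0.73, SE 0.15), and the transcription factor FOXM1 (0.89, SE 0.23) passed the threshold, and 5 did adjusted over the list alone. The DNA replication genes had 1 member higher, the primase subunit PRIM1 (0.84, SE 0.21), also 1 adjusted over the list alone, and a mean of 0.19 over 27 (adjusted p = 0.0325, and adjusted p = 0.852 with an estimated correlation). Relative to the weak bone lines, the parental array, strong and weak lung lines stood at -0.19, -0.18 and -0.88 for the TGF-beta list. For mitosis they stood at 0.17, 0.13 and -0.16 and for DNA replication at 0.23, 0.05 and -0.14. For collagens they stood at 0.08, 0.51 and -0.25 and for proteases at -0.16, 0.12 and -0.53. These levels compare signals across the separately divided sets. Rises here are strong against weak lung lines, and do not tell which group departed from the parental line.

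The other lists were not called between strong and weak lung lines. The interferon-stimulated genes (adjusted p = 0.355) moved both ways, with IRF7 at 1.65 and IFI27 at -2.25. Of the epithelial markers 1 of 18 passed, the claudin CLDN4 (-1.71), and the list's mean of -0.11 and median of 0.13 differed in sign (adjusted p = 0.729). The mesenchymal cadherin CDH11 rose (1.83, list adjusted p = 0.230). In the actin cytoskeleton list 3 of 25 fell and 0 rose, CALD1 (-1.01), MYH10 (-1.46) and the myosin light chain MYL9 (-1.22, list adjusted p = 0.324), and among p53 targets the repair factor XPC fell (-0.97, list adjusted p = 0.485). The YAP targets had adjusted p = 0.0714, the hypoxia genes 0.537 (mean 0.10, median -0.08), the immediate early genes 0.324 (mean 0.14, median -0.01), the NF-kB list 0.537, the ribosome list 0.629 and the cholesterol list 0.919. Of other cell types' markers, the leukocyte list had 1 of 15 higher, LAPTM5 (2.20, SE 0.20, list adjusted p = 0.155), and the endothelial and stromal list 3 higher and 1 lower of 11 (adjusted p = 0.234), the collagen COL1A1 (1.0, SE 0.23) among them.

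The weak lung lines differed among themselves in measures of RNA and array quality. The log2 ratio of the 3' to the 5' probe set was 0.35 for GAPDH and 0.40 for ACTB in SCP21 and 0.19 and 0.32 in SCP26, against -0.13 and 0.09 in SCP6 and at most 0.12 and 0.19 in the 4 strong lung lines. It was taken from the deposited ratios, so it is relative to the set's divisors and compares arrays within the set only. SCP6 had 4109 probe sets with a signal under 10, where SCP21 had 1384 and SCP26 1497. The count of genes past the threshold was 776 without SCP21, 997 without SCP26 and 614 without SCP6, and it was 528 without the strong line 4173, 503 without 4175 and 427 with the 7 lung lines alone in the fit. The collagen list kept its call without each line, whereas the TGF-beta and protease lists reached adjusted p = 0.0792 without SCP21 and the DNA replication list 0.808 without SCP26. Among named genes ADAMTS1, ANGPTL4, FOXM1, PRIM1, PTPRN2, SPANXB1, VCAM1, MYH10 and MYL9 lost their calls without at least 1 line, with the highest adjusted p 0.107, 0.0573, 0.0801, 0.0779, 0.0808, 0.0777, 0.0728, 0.0570 and 0.138. With the lung lines alone in the fit, calls were also lost for RACGAP1 (adjusted p = 0.0659), FOXM1 (0.0839), PRIM1 (0.0983), PTPRN2 (0.0772), VCAM1 (0.0848), CALD1 (0.0642), MYH10 (0.0509) and MYL9 (0.115).

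Strong bone lines were set against strong lung lines (n = 4 against 4) to ask what distinguishes the target organs. These groups lay in separate array sets, with spike-in means of 10.5 to 10.8 for strong bone and 9.57 to 10.1 for strong lung, so organ and array set cannot be told apart here. The cystatins CST1 (4.74, SE 0.86, adjusted p = 0.00227) and CST2 (3.27, SE 0.61) and the secreted trefoil proteins TFF1 (4.10, SE 0.51, adjusted p = 0.000319) and TFF2 (3.68, SE 0.45) were higher in bone lines. So were ADAMTS1 (3.64, SE 0.37), the lipase PNPLA4 (3.62, at least 4.48-fold), the Fc receptor FCGRT (3.41, at least 4.26-fold) and the disulfide isomerase AGR2 (3.29). Higher in lung lines were SPARC (-6.71, SE 0.39, adjusted p = 1.01e-06, at least 32.3-fold) and IL13RA2 (-5.68, SE 0.68, at least 14.8-fold). The others were the calcium-binding S100A2 (-3.66), PPL (-3.39, at least 3.02-fold), the adaptor APBA2 (-3.30, at least 3.60-fold), the collagen COL7A1 (-3.20) and the tumour antigen MAGEB2 (-3.04). The other of 2 PNPLA4 probe sets gave the opposite sign. In all, 2150 genes passed, 1191 higher in bone and 959 higher in lung lines (55.4% higher in bone). With a common trimmed mean, 1122 were higher in bone and 1442 in lung lines (43.8% higher in bone).

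In this comparison the bone metastasis genes were higher in bone lines (5 of 8 higher, 0 lower, 5 adjusted over the list alone, mean 1.58, adjusted p = 0.0013, and adjusted p = 0.396 with an estimated correlation). FST stood at 2.60 (SE 0.31) and CXCR4 at 1.92 (SE 0.30). The lung metastasis genes were lower (1 of 15 higher and 5 lower, 9 adjusted over the list alone, mean -1.26, adjusted p = 0.0121, and adjusted p = 0.396 with an estimated correlation). SPARC, IL13RA2 and TNC (-2.02, SE 0.36) were among the 5, and neither list is independent evidence. The collagens were lower (2 of 30 higher and 12 lower, 16 adjusted over the list alone, mean -0.61, adjusted p = 0.0317, and adjusted p = 0.526 with an estimated correlation). The crosslinking enzyme LOX (2.05, SE 0.30) was 1 of the 2 that were higher. The hypoxia and glycolysis genes were higher (8 of 25 higher and 1 lower, 9 adjusted over the list alone, mean 0.49, adjusted p = 0.022, and adjusted p = 0.934 with an estimated correlation). Among them were LOX, the mitophagy receptor BNIP3L (1.16, SE 0.29) and the glucose transporter SLC2A1 (0.71, SE 0.19, with adjusted p up to 0.0581 without 2274). The collagen and hypoxia calls were lost with quantile normalisation, with adjusted p = 0.0874 for each. The interferon-stimulated genes were not called (6 of 28 higher, 0 lower, adjusted p = 0.210), with the RNA sensor RIGI at 1.02 (SE 0.21), nor were the immediate early genes (6 higher and 2 lower of 26, adjusted p = 0.0623), with JUNB at 1.33 (SE 0.17).

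The strong-against-weak difference itself differed between bone and lung lines for 1101 genes, with 652 higher and 449 lower in bone than in lung (59.2% higher). PTPRN2, SPANXB1 and CSF3 fell in strong bone lines and rose in strong lung lines, with differences of differences of -8.18 (SE 1.57, adjusted p = 0.00468), -7.63 (SE 1.29) and -6.70 (SE 0.79). The long non-coding RNA LINC01711 (-3.06 in bone and 3.05 in lung), the receptor GPRC5C (-3.61 and 2.07) and SOX4 (-1.69 and 4.35) stood likewise, while SPARC (0.25 and 6.72) and SERPINA1 (-5.83 and 0.38) differed chiefly in 1 organ. In the other direction stood CEMIP (2.14 in bone and -3.54 in lung, difference 5.68, SE 0.72), C4BPB (2.91 and -2.52), MATN2 (2.09 and -3.04) and the transcription factor WT1 (2.18 and -2.90). The same held for PNPLA4 (2.0 and -2.98), the matrix protein EFEMP1 (2.42 and -2.36), SPINK4 (1.89 and -2.54) and MYH10 (2.70 and -1.46). Quantile normalisation gave 698 higher and 731 lower (48.8% higher) and the common trimmed mean, which moved the median of all genes from 0.03 to -0.10, gave 666 and 708 (48.5%).

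**Figure D3:**
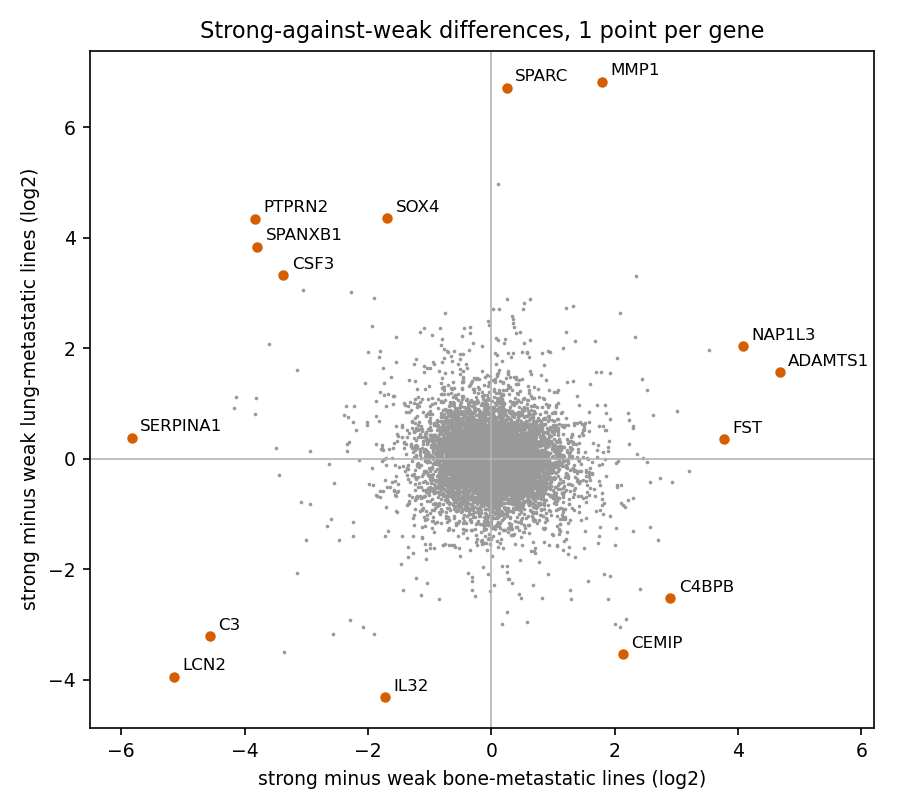
Each point is 1 of 9544 genes, with the log2 difference of strong minus weak bone lines (4 against 3) on the horizontal axis and of strong minus weak lung lines (4 against 3) on the vertical axis. LCN2 (-5.15 and -3.94) and C3 lie low in both, and PTPRN2 (-3.84 and 4.34), SPANXB1 and CSF3 lie at opposite ends.

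The lung metastasis genes carried the clearest difference between organs among the lists (12 of 15 lower, 0 higher, 12 adjusted over the list alone, mean difference -3.02, adjusted p = 1.03e-12, and adjusted p = 0.00518 with an estimated correlation). MMP1 stood at -5.03 (SE 0.78), ID1 at -3.76 (SE 0.43) and EREG at -2.59 (SE 0.33). The bone metastasis genes went the other way (4 of 8 higher and 1 lower, 6 adjusted over the list alone, mean 1.11, adjusted p = 0.0115, and adjusted p = 0.419 with an estimated correlation). FST at 3.42 (SE 0.47) and ADAMTS1 at 3.12 (SE 0.56) were higher and MMP1 lower. Neither list is independent evidence. The YAP targets differed upward (8 of 20 higher and 1 lower, 13 adjusted over the list alone, mean 0.93, adjusted p = 0.00011, and adjusted p = 0.419 with an estimated correlation). CRIM1 stood at 2.43 and the clotting initiator F3 at 2.90. The NF-kB list (0 higher and 6 lower of 21, 6 adjusted over the list alone, mean -1.30) and the collagens (2 higher and 9 lower of 30, 12 adjusted over the list alone, mean -0.85) differed downward, each with adjusted p = 0.00689, which became 0.420 and 0.415 as adjusted p with an estimated correlation. CCL20 stood at -5.10 and COL6A3 at -2.77.

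A further 5 lists had the same adjusted p of 0.0498 for this difference, and adjusted p = 0.420 for TGF-beta response and leukocyte markers and 0.644 for mitosis, DNA replication and cholesterol synthesis with an estimated correlation. The TGF-beta response (1 higher and 5 lower of 21, 8 adjusted over the list alone, mean -0.74) held TGFBI at -4.93. The leukocyte markers (0 higher and 2 lower of 15, 2 adjusted over the list alone, mean -0.61) held LAPTM5 at -3.75, the mitosis genes (0 and 2 of 32, 2 adjusted over the list alone, mean -0.21) RACGAP1 at -1.17, and the cholesterol genes (1 and 0 of 20, 0 adjusted over the list alone, mean 0.54) SCD at 2.70. The DNA replication genes had 0 higher and 1 lower of 27, with 0 adjusted over the list alone and a mean of -0.26. Each of these 5 calls was lost in 11 to 16 of 23 alternatives, and the NF-kB call without SCP21 (adjusted p = 0.0980). The SCD call was lost without any of 11 lines, at most at adjusted p = 0.114, and that of ADAMTS1 with log2 of the deposited ratios (adjusted p = 0.0519).

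Of the genes past the threshold for both organs, 25 were higher in both strong groups, where 20.7 would be by chance from 9544 genes, and 52 were lower in both, where 24.0 would. Higher in strong bone and lower in strong lung lines were 87 (34.1 by chance), and lower in bone and higher in lung lines 45 (14.6 by chance). The 2 sets of differences share no array, but they come from the same fit and share each gene's estimate of the spread. A gene with a small spread can therefore pass for both organs in any direction. The numbers by chance assume independence and may be too low, so an excess over them is not established. Across genes, which are not independent replicates, the 2 sets of differences correlated with Spearman's correlation -0.0731 and Pearson's r = -0.0584.

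The ploidy difference was then set against the strong-against-weak difference. In the 1833 pair, 511 of the 1072 genes that differed between strong and weak bone lines went the same way from modal-ploid to hyper-ploid (47.7%), and in the 4175 pair 345 of the 831 that differed between strong and weak lung lines did (41.5%). The crossed comparisons gave 47.3% for 1833 with lung and 44.3% for 4175 with bone. Over all genes, which are not independent replicates, Spearman's correlation was -0.00937 for 1833 with bone, -0.0169 for 1833 with lung, -0.0727 for 4175 with bone and -0.0325 for 4175 with lung, and Pearson's r was -0.0351, -0.0338, -0.0567 and -0.0633. Leaving out SCP6 moved the value of 4175 with lung to -0.179 and leaving out SCP26 to 0.0266, so its sign rested on single weak lines.

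The mean level of the bone metastasis genes lay 2.82 (SD 0.28, n = 4) above the weak bone lines in strong bone lines. It lay 1.24 (SD 0.30, n = 4) above them in strong lung lines and at -0.47 (SD 0.15, n = 3) in weak lung lines. All levels of lung lines and of 4175 sublines against weak bone lines, and of the others against weak lung lines, compare signals across the separately divided sets. The parental array stood at 0.44. The modal-ploid sublines stood at 2.62 for 1833 and 1.97 for 4175, and the hyper-ploid sublines at 2.65 and 1.23. The mean level of the lung metastasis genes lay above the weak lung lines by 2.67 (SD 0.26, n = 4) in strong lung lines, by 1.75 (SD 0.28, n = 3) in weak bone lines and by 1.41 (SD 0.23, n = 4) in strong bone lines. The modal-ploid sublines stood at 1.69 for 1833 and 3.05 for 4175, and the hyper-ploid sublines at 1.5 and 2.48.

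**Figure D4:**
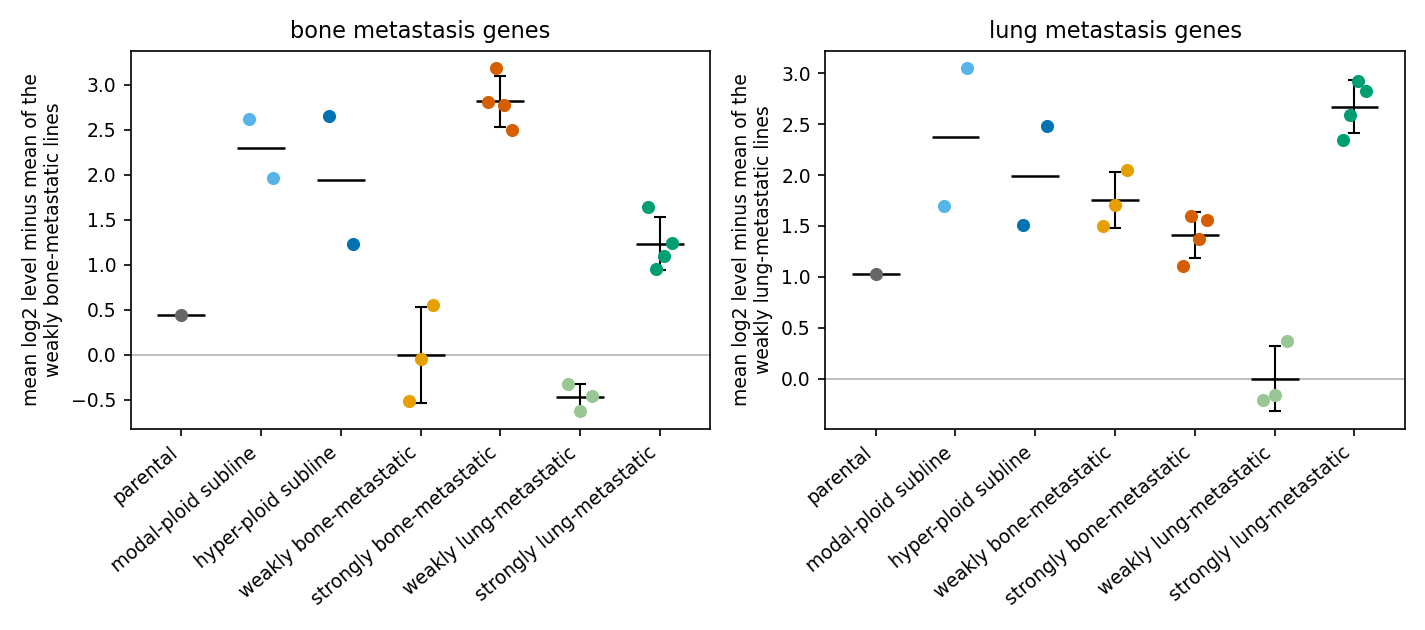
Mean log2 level of the bone metastasis genes (8 genes, relative to the weak bone lines) and of the lung metastasis genes (15 genes, relative to the weak lung lines), 1 point per array, with lines at group means and bars of 1 SD where a group has 3 or 4 arrays. The 4 strong bone lines average 2.82 for the first list and the 4 strong lung lines 2.67 for the second.

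Correlation between arrays over the 9544 genes put each ploidy subline nearest to its sibling, with r = 0.978 for the 1833 pair and 0.970 for the 4175 pair. The modal-ploid and hyper-ploid sublines of 1833 correlated with the line 1833 at r = 0.936 and 0.933, and those of 4175 with 4175 at 0.943 and 0.932. Mean r within groups was 0.968 for strong lung, 0.958 for weak bone, 0.955 for strong bone and 0.930 for weak lung lines. The parental array was nearest to SCP6, with r = 0.953.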

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

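The tests on neighbouring genes that removed the trend with expression or used distant genes, and both tests on the genes higher in strong lung lines, were chosen only after the result was seen. HLA-DRB1 and ALPP were likewise chosen after their values were seen.

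A single line stood apart in 6 of the 124 sets of 4 lines examined, where chance gives about 1 in 20, so this number is about what chance gives. PTPRN2 had a signal of 197 in the strong bone line 2274 and 5.25 to 10.0 in the other 3 (gap over range 0.912), and 14.8 in the strong lung line 4142 against 1091 to 1472 in the others (0.924). WDR43 was at 399 in strong bone line 2269 and 565 to 579 in the others (0.933). In the strong lung lines TNC was at 687 in 4175 against 331 to 371 (0.845), CCN2 at 3309 in 4180 against 4037 to 4045 (0.989), and HLA-DRB1, a class II antigen chain, at 1069 in 4180 against 815 to 827 (0.947).

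The difference between strong and weak lines was itself tested for a difference between bone and lung lines, and 1101 genes passed. Of 100 drawn regroupings within the bone and within the lung lines, 1, the real one, gave as many, and the highest other gave 116. A share below 1 in 100 cannot be shown with this number of draws. For the comparisons themselves, 1 of 35 splits of the bone lines gave as many genes as the real 1072. The highest other gave 369, with strong line 2269 grouped with the 3 weak lines. For lung lines 1 of 35 did (real 831, highest other 28), and for strong bone against strong lung lines 1 of 35 did (real 2150, highest other 1). With 35 splits a share below 1 in 35 cannot be shown, so chance is unlikely but not excluded. Mixed splits also put the group difference into the spread between lines, which keeps their counts low. The splits take the lines as exchangeable, and descent shared within a group was not tested. For strong bone against strong lung lines, organ and array set cannot be told apart.

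Among the genes whose strong-minus-weak difference was higher in bone than in lung lines were CEMIP (5.68), C4BPB (5.43), MATN2 (5.13), WT1 (5.08), PNPLA4 (4.98), EFEMP1 (4.78), SPINK4 (4.43) and MYH10 (4.16). Those whose difference was lower in bone than in lung lines were PTPRN2 (-8.18), SPANXB1 (-7.63), CSF3 (-6.70), SPARC (-6.46), SERPINA1 (-6.22), LINC01711 (-6.11), SOX4 (-6.04) and GPRC5C (-5.67). Of metastasis list members, FST (3.42), ADAMTS1 (3.12), MMP1 (-5.03), ID1 (-3.76) and EREG (-2.59) differed. Of YAP targets CRIM1 (2.43) and F3 (2.90) did, and among the other lists CCL20 (-5.10), TGFBI (-4.93), COL6A3 (-2.77), LAPTM5 (-3.75), SCD (2.70) and RACGAP1 (-1.17).

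As lists, the means of this difference were 1.11 for the bone metastasis genes, -3.02 for the lung metastasis genes, 0.935 for YAP targets, 0.537 for cholesterol synthesis, -1.30 for NF-kB and inflammatory cytokines and -0.854 for collagens. They were -0.738 for the TGF-beta response, -0.611 for leukocyte markers, -0.256 for DNA replication and -0.209 for mitosis. ALPP, an alkaline phosphatase, stood at -4.56 in the 1833 pair of ploidy sublines and 0.03 in the 4175 pair (difference -4.60, SE 0.46, adjusted p = 0.00103 in limma). With 1 array per arm this p rests on the spread within the other groups and does not establish a difference between the pairs.

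By correlation, each ploidy subline was nearer to the sublines of the other line than to its own line of origin, with r higher by 0.00875, 0.00972, 0.00835 and 0.00447. By distance the hyper-ploid 4175 subline was not, at 68.1 from its origin and 69.9 from the other hyper-ploid subline. Over the brighter 4772 genes the mean excess was -0.00399, from -0.00825 to 0.00341, and positive for the hyper-ploid 4175 subline alone. Over the dimmer 4772 the excess was 0.0321 to 0.0810, so spread in dim genes may produce most of it. Effects on single probe sets stay open, since the shift shared by the 4 subline arrays correlated with r = 0.392 between probe sets of a gene (3136 genes), against 0.430 to 0.652 for the strong and weak contrasts, and the spike-in levels of these 4 arrays cannot be told apart from their being ploidy sublines. Raised DNA content is no explanation of a shift that the modal-ploid sublines share, and no biological explanation was tested.

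Genes close together in the genome differed alike. The correlation of a gene's difference with the mean of genes 3 to 10 places away was 0.225 for strong against weak bone lines, 0.178 for lung lines, 0.170 for strong bone against strong lung lines, 0.0985 for the 1833 pair and 0.218 for the 4175 pair, above all of 1000 shuffles (highest 0.0555). Removing the trend with mean expression left a smallest value of 0.0996, and genes 30 to 60 places away gave a smallest value of 0.121, which argues against clusters of expression level and short-range co-regulation as the whole cause. Regional differences in gene copy number between sublines could produce this and stay a hypothesis, since no copy number was measured and GC content was not testable. Chromosome medians were taken of the differences with the trend with mean expression removed. They reached 0.54 (141 genes) and -0.26 (426) for bone lines, and 0.25 (537) and -0.33 (141) for lung lines. For strong bone against strong lung lines they reached 0.35 (141) and -0.20 (340). In the 1833 pair they reached 0.18 (360) and -0.13 (365), and in the 4175 pair 0.19 (426) and -0.28 (340).

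Genes higher in strong lung lines were lower in the hyper-ploid than the modal-ploid subline of 4175, with a median of -0.325 and 234 of 314 lower. Random lists matched on mean expression over all arrays gave -0.176 to 0.0269 (median -0.068). Level in the compared 4175 sublines themselves was not matched, so this cannot decide about expression level as the cause. Quantile normalisation left -0.200, which argues against a narrower range of the hyper-ploid 4175 array as the whole cause. In 4175 the genes higher and lower in strong bone lines also stood low, at percentiles 0.15 and 0.36. They lay nearer to their random medians (-0.155 and -0.130 against -0.103 and -0.070). Genes lower in strong lung lines stood above all random lists (-0.012). In the 1833 pair the genes higher in strong lung lines had a median of 0.067, and those higher in bone lines stood low (0.016, percentile 0.01). Ploidy of the 4175 subline stays open as a hypothesis with 1 array per arm, as does any other difference between these 2 cultures.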

How the results depend on the processing

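The alternatives were chosen before the data were examined, except the common trimmed mean and log2 of the deposited ratios, chosen after seeing the data. Of 180 named gene results, 179 kept their direction and 142 also their side of the threshold in all alternatives, and the listed groups past the threshold kept their direction. The exception was TRIM22 in ploidy sublines (main -0.82, not past the threshold), from -1.72 without replicate 1 (1833) to 0.082 without replicate 2 (4175), since its fall was in 4175 alone. Here the lone sublines left were assumed to vary like the other groups. Centring on the median changed no count by construction. Signals under the 40th percentile limit what dim genes show.

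The ploidy count of 1 became 0 with quantile normalisation, a pseudocount of 1, no filter, the trimmed mean, log2 ratios, all probe sets and no replicate block pairing sublines of a line. With all 19 arrays in the fit it stayed 1, but the gene was ALPP (-2.27, adjusted p = 0.00123) and PRKCZ lost its call (adjusted p = 0.192). It became 27 with the filter at the 60th percentile, and leaving out a pair gave 0 to 1 genes and 2 to 5 lists, the 2 without replicate 2 (4175). Using all probe sets gave 1671 genes for bone, 1249 for lung, 3792 for strong bone against strong lung and 1743 for the difference between organs, with more sets tested than genes. An adjusted p below 0.1 gave 1685 for bone, and only the lines of the 2 groups 427 for lung, with fewer lines for the spread. Quantile normalisation left 2 lists of 4 for strong bone against strong lung, and a pseudocount of 1 and log2 ratios each left 5 of 10 for the difference between organs. For these the cause was not tested.

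Spearman's correlation between ploidy and strong-against-weak differences moved with quantile normalisation to -0.0350 (1833 with bone), -0.0339 (4175 with bone) and -0.0866 (4175 with lung), and with the filter at the 60th percentile to -0.0273, -0.0463 and -0.142. That filter, which keeps brighter genes, turned the mean excess in similarity from 0.0078 to -0.00747. Leaving out each line gave ranges of -0.0277 to 0.0063 (1833 with bone), -0.0445 to 0.0249 (1833 with lung), -0.123 to -0.0396 (4175 with bone) and -0.179 to 0.0266 (4175 with lung).

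Leaving out each line gave 532 to 1411 genes for bone (545 without 2293, 532 without 2295, 605 without 2296, 705 without 2274) and 503 to 997 for lung (528 without 4173, 503 without 4175). It gave 1470 to 2653 for strong bone against strong lung and 758 to 1397 for the difference between organs. The lists ranged from 2 (without 2274) to 6 for strong bone against strong lung. They ranged from 5 (without 1833) to 9 for the difference between organs, with 6 without 2293, 2274, 2268 or 4175.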

Other observations

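The genes of the next paragraph were chosen after their values were seen.

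Several single genes of antigen presentation differed in the same direction for both organs. No list of such genes was tested, and HLA-DOA, HLA-DQB1, HLA-DRB4 and CIITA, for example, passed for neither organ. The invariant chain CD74 differed by -2.24 (SE 0.27, adjusted p = 0.00026, limma, n = 4 against 3) in bone and -1.39 (SE 0.27, adjusted p = 0.00613) in lung lines. HLA-DRB1, whose probe set is shared with family members, differed by -3.14 (SE 0.39, adjusted p = 0.000303) and -2.08 (SE 0.39, adjusted p = 0.00497). HLA-DPA1 differed by -2.29 (adjusted p = 0.00638) and -2.93 (adjusted p = 0.00125), and HLA-DPB1 by -2.07 (adjusted p = 0.0115, and 0.0502 without 2293) and -3.04 (adjusted p = 0.00104). HLA-DRA fell by 3.0 in bone lines (adjusted p = 0.00104) and stood at -1.48 in lung lines, where it did not pass (adjusted p = 0.0564, from 0.0255 to 0.174 over the other settings). None of these 5 passed for a difference between organs (adjusted p = 0.141 to 0.570). Higher in the strong lines of both organs, by over 4-fold in signal + 16, were ROBO1 (2.35 in bone and 3.31 in lung), the disulfide isomerase AGR2 (2.08, with adjusted p = 0.0158, from 0.00141 to 0.0660 over the other settings and 0.0778 without 2293, and 2.63), the cell cycle regulator RGCC (2.33 and 2.19, the latter with adjusted p = 0.0645 with only the lung lines in the fit) and NAP1L3 (4.09 and 2.04). For genes at or below the 40th percentile in the weak lines, such as ROBO1 in lung lines, a 4-fold change in signal is not established. The lung call of NAP1L3 (adjusted p = 0.0494) was lost without any of 11 lines, at most at 0.194 without SCP6.

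The parental array was in no group comparison. Its spike-in level lay among those of the bone lines (10.5 to 10.9), and its mean over the lung metastasis genes was 1.03 above the weak lung lines, a comparison across the separately divided sets.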
